A study of Mus musculus with 8 samples.

How the data were processed

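The libraries held polyadenylated RNA extracted with a column kit for small cell numbers and amplified with the Smart-Seq2 protocol, which copies full-length transcripts by PCR and marks neither molecules nor strand. Per the submitters' processing notes, reads were handled with STAR 2.7.8a and RSEM 1.3.0 on GRCm39. The authors deposited 1 table of whole-number counts for 53700 genes in 8 libraries, with no normalization. The annotation release, the read filters and how RSEM's estimates became whole numbers are not given in the sources used here. Counting was taken as unstranded, so overlapping and antisense genes, paralogs and pseudogenes share reads to an unknown degree. A mouse annotation of an earlier build was used only for the order of genes along chromosomes, and no coordinates were taken from it. In the table, 101 gene symbols were duplicated, and genes were followed by identifier.

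Each library's cell type and genotype came from its labels, and its column was matched by name. Total counts ran from 28871700 to 47206000, a 1.635-fold range, and 13510 to 14781 genes had a count. The 10 most abundant genes took 8.53% to 10.4% of counts, mitochondrial genes 1.76% to 2.56%, and the 18S rRNA gene Rn18s 3.43% to 5.38%. At this depth 10 CPM corresponds to at least 289 counts, so counting error is small for most genes named. Detection floors were set at 3 counts per library, and a fold against libraries all at 0 was computed against the mean of those floors and is given as "at least". Such a bound covers counting error only, and not other spread between libraries. Levels are CPM after TMM scaling.

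Counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, installed default settings) in R 4.3.3, with TMM factors, filterByExpr by cell type (12132 genes, holding 99.458% of counts) and Benjamini-Hochberg adjustment at 0.05. The installed default is the older quasi-likelihood method, and the design did not fix that option, so the bias-adjusted method was run beside it. HSC and MPP were compared with genotype as a block (3 residual degrees of freedom). Nfat5 loss and Ifnar1 loss were tested with cell type and both genes as terms (4 residual degrees of freedom), a design with 4 disjoint pairs of libraries per factor. The 3 interactions each had 3 residual degrees of freedom. For all contrasts the error comes from terms left out of the model, since no group was replicated. Common dispersion was 1.05 to 1.14.

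Of 20 gene lists fixed before the data were examined, along with the designs, the naming rule and most alternative settings, 17 had at least 3 measured members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2. The preset correlation was 0.01, and camera with an estimated correlation and fry were run beside it. The lists covered the interferon response (59 of 67 genes measured), antigen presentation (24 of 24), osmotic stress (10 of 15), stem cell identity (27 of 30), progenitor priming (22 of 25), proliferation (34 of 34), immediate early genes (14 of 20), p53 targets (20 of 24), NF-kB inflammation (16 of 23), ribosome biogenesis (24 of 24) and oxidative phosphorylation (27 of 27). Marker lists covered megakaryocytes (11 of 15), erythroid cells (9 of 12), B cells (7 of 11), neutrophils (11 of 12), monocytes and macrophages (8 of 13), and mast cells and basophils (3 of 9). T and NK cells (1 of 13) and stroma and endothelium (1 of 10) had too few measured members to test, and a sex-linked list served as a check. List medians were set against 10000 random lists of the same size drawn from 20 expression bins, with their central 95%.

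Named genes followed a rule. Nfat5 and Ifnar1 came first. Each tested contrast then gave the 10 largest positive and 10 largest negative changes among calls with at least 10 CPM and the same direction in all 4 pairs, or the 5 genes of smallest p where fewer than 5 were called. Predicted genes, pseudogenes, antigen receptor segments, Y-linked genes and Xist were left out of these. For N5 against WT and DKO against IFNAR, the 5 highest and 5 lowest genes at 2-fold or more the same way in both cell types were named. Up to 4 members of each list with the largest log2 fold change completed the rule, and a few further list members (among them Mpo, Pf4, Mcm7, Ighm, Akr1b3, Slc6a6, Irf9, Ly6a and Lgals3bp) were chosen after their values were seen. Some genes that the rule names are not reported here. Single libraries were compared as log2 ratios of CPM with a prior count of 2, without a test, and the intervals of shares are exact binomial.

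The alternative settings were DESeq2 size factors (RLE), no filter, a filter of 10 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, leaving out each library, models without a block or term, summing HSC and MPP per genotype, genotype as a random block, the libraries with the other gene intact or lost, and for single libraries prior counts of 0.5 and 5, thresholds of 5 and 50 CPM, and thinning to the smallest total. The bias-adjusted method, a mean of at least 50 CPM and limma-trend with robust variances were added after seeing the data. RLE scaling moved the median of all genes by 0.0296 (log2) in HSC versus MPP.

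The procedures were tested on simulated counts for 12132 genes with 200 changed, drawn only from genes with a mean of at least 10 CPM. With edgeR as used here, 20% of 4-fold and 59% of 16-fold changes were recovered for HSC versus MPP, 34% and 64% for Nfat5 loss, and 26% and 65% for Ifnar1 loss, with 3, 1 and 0 false calls. For interactions, recovery of 4-fold and 16-fold changes was 0% and 15% (Nfat5 by Ifnar1), 0% and 24% (Nfat5 by cell type), and 1% and 20% (Ifnar1 by cell type). False calls there were 1 of 16, 1 of 25 and 5 of 26 (6.25%, 4% and 19.2%). Of DESeq2's calls on the same simulations, 60.6% to 80.9% were false, against 11.1% to 20% for bias-adjusted edgeR and 0% to 16.7% for limma-voom. A simulated list of 60 genes lowered by 1 on the log2 scale for Ifnar1 loss gave a camera p of 1.30e-12.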

Results

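Polyadenylated RNA was measured in 8 pools of sorted mouse bone marrow cells, 1 library for each combination of 2 cell types and 4 donor genotypes. Haematopoietic stem cells (HSC) lacked surface CD48 and carried CD150, and multipotent progenitors (MPP) showed the opposite pattern. Both came from the LSK gate of lineage-negative marrow cells with Sca-1 and Kit on their surface. Donor marrow had intact Nfat5 with Vav-Cre (WT), loss of Nfat5 in blood-forming cells (N5), deficiency of Ifnar1 (IFNAR), or both defects (DKO). Donor cells were sorted from irradiated wild-type recipients 13 weeks after transplantation, with 5 mice per pool. Nfat5 encodes a transcription factor of the osmotic stress response, and Ifnar1 encodes a chain of the type I interferon receptor. The groups address how HSC and MPP differ, whether NFAT5 loss alters their transcripts, and whether such an effect requires the receptor.

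Total counts were 34836900, 30874300, 38317700 and 47206000 in the HSC libraries of WT, N5, IFNAR and DKO, and 30648600, 28871700, 37374100 and 35167500 in the MPP libraries, in the same order. Each factor was tested across libraries matched on the other factors, because each group had 1 library. The p-values therefore measure only the spread between these libraries. HSC libraries resembled each other less than MPP libraries did. Pearson correlations of log2 library-scaled counts (CPM) across genes, which are not independent replicates, ran from 0.604 to 0.656 over 6 HSC pairs and from 0.725 to 0.773 over 6 MPP pairs. Across cell types they ran from 0.599 to 0.638 over 16 pairs. The first principal component held 23.9% of the variance and separated the cell types, while the next held 18.6% and ran from the HSC library labelled WT to the HSC library labelled IFNAR. The female transcript Xist lay between 496 and 1160 CPM in all 8 libraries, and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 0 counts in all 8.

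The targeted genes did not follow the genotype labels. Nfat5 (ENSMUSG00000003847.17) had 33.2 CPM (95% exact Poisson interval 31.3 to 35.1) in the HSC library labelled WT and 22.7 CPM (21.01 to 24.4) in the one labelled N5. In HSC it had 3.12 CPM (2.59 to 3.72) in the library labelled IFNAR, where Nfat5 should be intact, and 35.5 CPM (33.9 to 37.3) in the library labelled DKO. In MPP it had 5.59 CPM (4.78 to 6.50) under WT, 7.69 CPM (6.71 to 8.78) under N5, 0.193 CPM (0.0774 to 0.397) under IFNAR and 11.5 CPM (10.4 to 12.7) under DKO. Ifnar1 (ENSMUSG00000022967.14) had 122 CPM (118 to 126), 126 CPM (122 to 130), 113 CPM (109.9 to 117) and 35.1 CPM (33.4 to 36.8) in the HSC libraries labelled WT, N5, IFNAR and DKO. In the MPP libraries it had 37.2 CPM (35.02 to 39.4), 87.9 CPM (84.5 to 91.4), 43.8 CPM (41.6 to 46.0) and 125 CPM (122 to 129) in that order. The deleted exons are not given in the sources used here, and counts summed over a gene cannot separate them from exons that remain. Libraries are therefore named by their labels, and every direction drawn below for Nfat5 or Ifnar1 rests on those labels, which these transcripts did not follow. Intervals and detection floors cover counting error only, which understates the spread between libraries. Pairs of HSC libraries had a median absolute log2 ratio of 1.07 at 10 to 50 CPM and 0.635 at 50 to 100 CPM. Counting alone gives 0.045 and 0.0271.

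**Figure D1:**
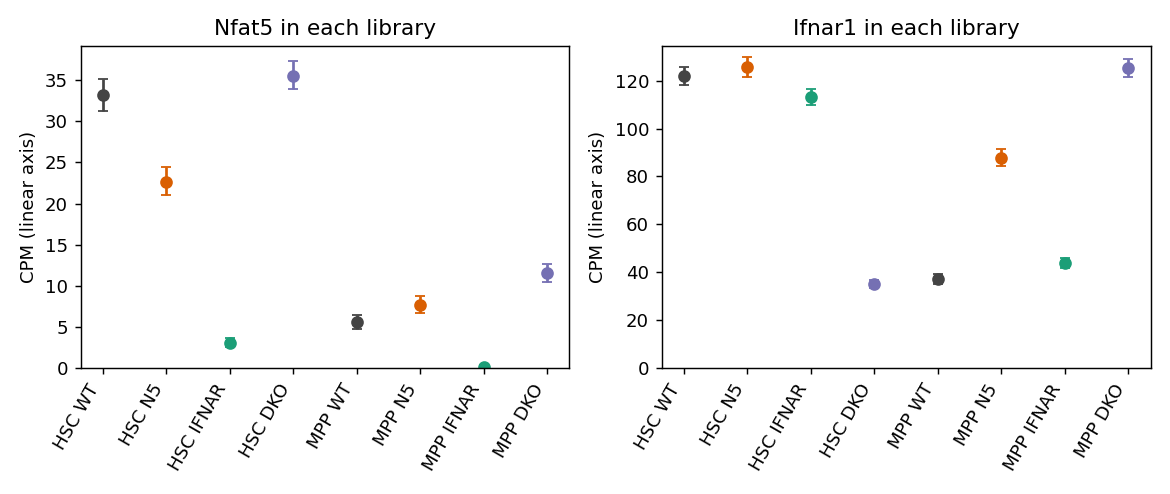
Nfat5 and Ifnar1 in each of the 8 libraries, as CPM on a linear axis with 95% exact Poisson intervals (counting error only). Nfat5 was lowest in the libraries labelled IFNAR (3.12 CPM in HSC, 0.193 CPM in MPP), and Ifnar1 was 125 CPM in the MPP library labelled DKO.

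The comparison of HSC with MPP asked which transcripts separate the stem cell gate from the progenitor gate. Dntt, the terminal transferase of early lymphoid cells, fell from 511 ± 212 CPM in MPP to 0.00725 ± 0.0145 CPM in HSC (mean ± SD, n = 4 libraries per cell type here and below). Cd34, a surface sialomucin of progenitors, fell from 1467 ± 185 to 244 ± 51.4 CPM. Genes of stem cell identity rose together in HSC, with 26 of 27 measured members higher and a median log2 difference of 2.94 (camera adjusted p = 7.40e-23). Genes of progenitor lineage priming fell together, with 22 of 22 lower and a median of -5.85 (camera adjusted p = 4.47e-17). Megakaryocyte genes also rose in HSC, with 10 of 11 higher and a median of 2.44, and proliferation genes fell, with 32 of 34 lower and a median of -0.98 (camera adjusted p = 2.47e-09 for each). These p-values were at camera's preset correlation. With an estimated correlation, camera gave adjusted p = 0.0233 for stem cell and priming genes, 0.0374 for megakaryocyte and 0.0416 for proliferation genes. The stem cell list holds Slamf1 and the priming list holds Cd48, both genes of sorting markers.

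Among stem cell genes, the transcription factor gene Mycn had 485 ± 110 CPM in HSC and 64.5 ± 21.1 CPM in MPP. Fgd5 had 40.4 ± 18.1 against 0.869 ± 1.74 CPM, and Ndn 28.4 ± 8.79 against 0, at least 305-fold higher. Neo1 had 15.4 ± 10.6 CPM against 0, at least 166-fold higher. Slamf1, which encodes the sorting marker CD150, had 74.5 ± 18.2 against 0.00688 ± 0.0138 CPM, and Cd48, the other sorting marker, 1.59 ± 3.18 against 249 ± 36.7 CPM. Among priming genes, the granule peroxidase gene Mpo had 124 ± 134 CPM in HSC and 6677 ± 2236 CPM in MPP. Csf1r, the M-CSF receptor, had 0.00725 ± 0.0145 against 40.1 ± 30.1 CPM, and Ly86 had 0 against 16.2 ± 10.3 CPM, at least 200.1-fold lower. The platelet gene Cavin2 had 104 ± 46.8 CPM in HSC and 0 in MPP, at least 1116-fold higher, and Rab27b had 58.7 ± 21.5 against 1.42 ± 2.74 CPM. The platelet factor gene Pf4 had 80.8 ± 34.9 against 3.35 ± 2.08 CPM, and Gata1 29.4 ± 21.4 against 4.56 ± 5.87 CPM. The topoisomerase gene Top2a, used in dividing cells, had 206 ± 51.9 against 672 ± 119 CPM, and the replication licensing gene Mcm7 had 451 ± 21.2 against 862 ± 49.0 CPM. Cenpf had 16.8 ± 31.3 against 30.7 ± 27.6 CPM, Cenpe 8.24 ± 8.60 against 33.6 ± 23.1 CPM, and E2f1 went the other way at 15.6 ± 7.41 against 4.69 ± 2.14 CPM.

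Type I interferon response genes rose in HSC, with 42 of 59 higher and a median of 0.68 (camera adjusted p = 3.89e-06 at the preset correlation and 0.0374 with an estimated correlation). The antiviral gene Oas3 had 88.2 ± 44.8 against 13.9 ± 17.3 CPM. Ifit2 had 33.2 ± 26.7 against 8.07 ± 11.3 CPM, Ifi44 37.7 ± 20.04 against 27.4 ± 32.5 CPM, and Ifi209 lay the other way at 3.15 ± 6.30 against 27.3 ± 28.4 CPM. Antigen presentation genes rose by camera, with 15 of 24 higher, a median of 0.11 and a mean of 0.37. Camera gave them adjusted p = 0.00572 at its preset correlation and lost the call otherwise (adjusted p = 0.411 with an estimated correlation). Of these, H2-T22 had 264 ± 84.1 against 121 ± 55.5 CPM, H2-T23 415 ± 118 against 174 ± 30.3 CPM, and the class I transactivator gene Nlrc5 113 ± 31.1 against 45.5 ± 21.03 CPM. B cell genes fell in HSC at the preset correlation, with 6 of 7 lower and a median of -5.26. Camera gave them adjusted p = 0.000144, a call that was lost with adjusted p = 0.0791 with an estimated correlation. They included the heavy chain gene Ighm at 18.1 ± 13.5 against 1294 ± 473 CPM and the surrogate light chain gene Igll1 at 0 against 9.66 ± 6.32 CPM, at least 119-fold lower. Monocyte and macrophage genes fell too, with 7 of 8 lower and a median of -3.31. Camera gave them adjusted p = 0.000190, again lost (adjusted p = 0.0750 with an estimated correlation). Their member Ccr2, a chemokine receptor gene, had 0 against 32.3 ± 7.85 CPM, at least 398-fold lower, and F13a1, which encodes a coagulation factor subunit, 0 against 71.7 ± 41.5 CPM, at least 884-fold lower.

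Of 12132 genes tested with edgeR, 2 passed, and both were lower in HSC in 4 of 4 pairs: Dntt (log2 fold change -15.55, SE 0.50, adjusted p = 0.00430) and Cd34 (-2.60, SE 0.12, adjusted p = 0.0158). An unadjusted p under 0.05 was reached by 1225 genes, where 607 were expected by chance. Among the next by p in edgeR, which did not pass, were Nkg7, a cytotoxic granule gene, with 46.5 ± 13.9 against 333 ± 37.0 CPM (adjusted p = 0.0514), and Mycn (adjusted p = 0.0547). Of 17 lists tested, 8 passed with camera at its preset correlation. With an estimated correlation, camera kept 5 of these, all but antigen presentation, B cell and monocyte and macrophage genes. Adjusted over the list alone, edgeR called 21 stem cell, 17 priming, 21 proliferation, 8 megakaryocyte, 2 interferon, 8 antigen presentation, 3 erythroid, 3 mast cell and basophil, 1 immediate early, 1 B cell and 1 monocyte and macrophage genes, 86 calls over the lists with shared genes counted in each. Adjusted over all genes, only Dntt and Cd34 of these lists passed. DESeq2 called 1880 genes and limma-voom 156, while leaving out any 1 library left 0 calls in edgeR, with smallest adjusted p from 0.0717 to 0.368.

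The other lists did not pass in camera, although all 3 measured mast cell and basophil genes and erythroid genes, among them Hbb-bt and Car2, were called by edgeR adjusted over the list alone. Mast cell and basophil genes had a median of -5.76 over 3 measured members (adjusted p = 0.510), with the protease gene Cpa3 at 5.89 ± 7.43 in HSC against 68.7 ± 38.8 CPM in MPP, Mcpt8 at 3.17 ± 6.34 against 13.5 ± 8.65 CPM, and Gata2, shared with the stem cell list, at 418 ± 111 against 133 ± 38.2 CPM. Erythroid genes differed in sign between median (0.99), mean (-1.37) and test (up, adjusted p = 0.510 by camera). The haemoglobin gene Hbb-bt had 80.4 ± 19.6 against 31.4 ± 11.5 CPM, Car1 6.99 ± 4.68 against 111 ± 75.1 CPM, and Klf1 3.20 ± 6.35 against 24.0 ± 16.5 CPM. Camera gave adjusted p = 0.218 for oxidative phosphorylation (median -0.17), 0.474 for ribosome biogenesis (-0.16), 0.228 for osmotic stress (-0.19) and 0.603 for p53 targets (-0.75). Oxidative phosphorylation passed with fry (adjusted p = 0.0160) and was lower in 4 of 4 pairs. For immediate early genes (0.18) camera gave adjusted p = 0.228. Among them Egr1 had 70.8 ± 55.3 against 4.10 ± 5.81 CPM and was called by edgeR adjusted over the list alone. The NF-kB inflammation list had a median of 0.28, a mean of -1.09 and a downward test, and the neutrophil list a median of 0.14, a mean of -0.42 and an upward test (adjusted p = 0.817 and 0.801 by camera). Only 1 member of each of the other marker lists was measured, Nkg7 for T and NK cells and the endothelial gene Emcn for stroma and endothelium, so neither list was tested. Emcn had 0, 0, 0.102 and 75.6 CPM in the HSC libraries labelled WT, N5, IFNAR and DKO, and 22.8, 4.99, 43.6 and 29.7 CPM in MPP.

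**Figure D2:**
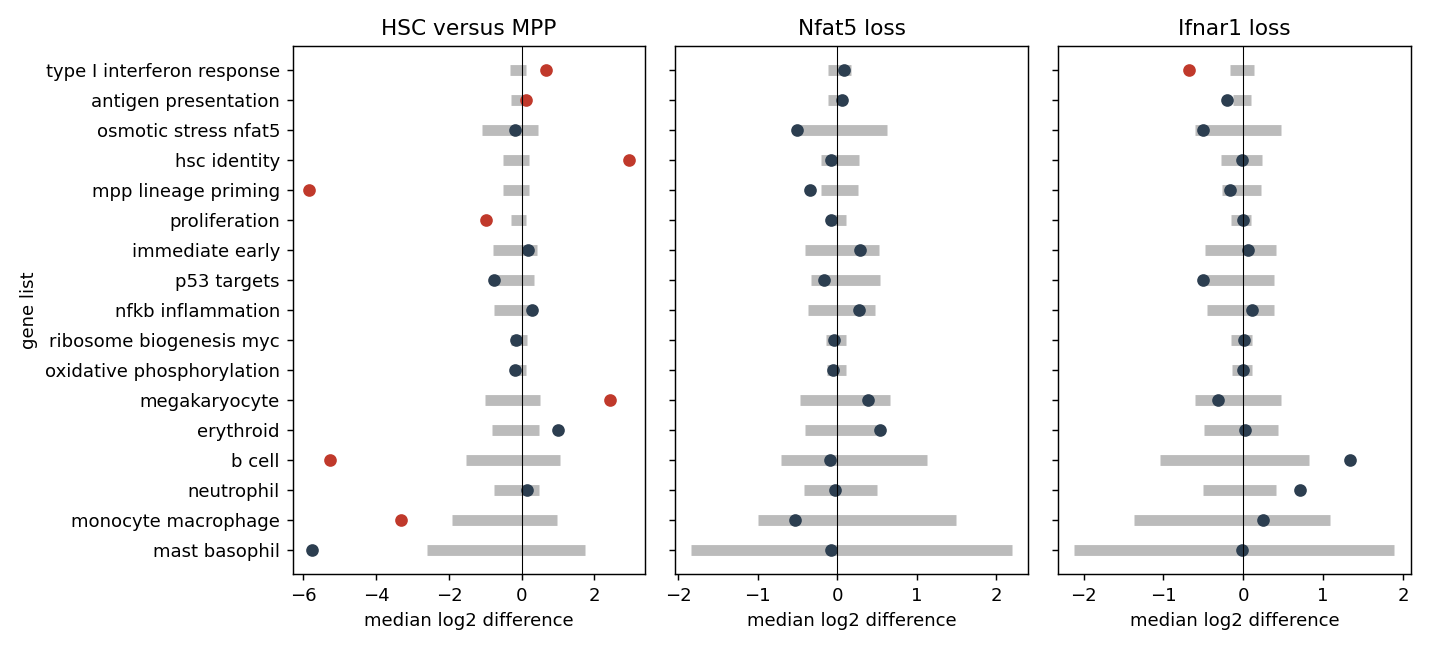
Median log2 difference of each gene list (points) for HSC versus MPP, Nfat5 loss and Ifnar1 loss, with the central 95% of 10000 random lists matched on expression (grey bars) and lists past the camera test in red. Red points number 8, 0 and 1 in the 3 panels, and the interferon list lies at -0.69 for Ifnar1 loss.

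Nfat5 loss was examined by setting the libraries labelled N5 and DKO against those labelled WT and IFNAR. No gene passed edgeR in this comparison, so the values that follow are levels without a called change, and Nfat5 itself did not follow the labels. Osmotic stress genes, the classical targets of NFAT5, had a median log2 difference of -0.50 against -0.48 to 0.62 in random lists and a mean of -1.005, with 7 of 10 measured members lower (camera adjusted p = 0.289). For Ifnar1 loss the list had a median of -0.50 against -0.61 to 0.48, with 8 of 10 lower (camera adjusted p = 0.703). Sgk1, a kinase gene induced by hypertonic stress, had 0.290 ± 0.579 CPM in the libraries labelled Nfat5-deficient and 29.4 ± 26.0 CPM in the others, lower in 4 of 4 pairs (mean ± SD, n = 4 libraries per side). Each side holds HSC and MPP libraries, so these SDs include the difference between cell types, which the model takes out. S100a4 had 4.29 ± 3.66 against 14.4 ± 5.38 CPM, also lower in 4 of 4 pairs, and the heat shock gene Hspa1a 5.36 ± 6.24 against 16.7 ± 11.3 CPM. Akr1b3, the aldose reductase that makes sorbitol, had 246 ± 27.9 against 237 ± 70.9 CPM, and the taurine transporter gene Slc6a6 76.1 ± 36.6 against 115 ± 30.3 CPM.

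The 5 genes of smallest p did not pass. The inositol pyrophosphate kinase gene Ppip5k1 had 20.1 ± 10.9 CPM in the libraries labelled Nfat5-deficient and 0.00827 ± 0.0165 CPM in the others, higher in 4 of 4 pairs. Dynlt2a2 had 1.54 ± 0.846 CPM against 0, at least 17.9-fold higher. Cenpa, the centromeric histone H3 variant, had 55.2 ± 13.8 against 119 ± 40.2 CPM, lower in 4 of 4 pairs. Slc36a1, an amino acid transporter gene, had 0.111 ± 0.186 against 6.09 ± 7.73 CPM, and Zfp820 0.0251 ± 0.0315 against 21.3 ± 14.9 CPM. Among list members, the granulocyte precursor gene Ms4a3 had 48.1 ± 59.6 against 96.7 ± 114 CPM, lower in 4 of 4 pairs, and the platelet glycoprotein gene Gp5 had 41.8 ± 42.4 against 14.6 ± 12.4 CPM, higher in 4 of 4 pairs. Cenpf had 5.33 ± 6.997 against 42.1 ± 30.3 CPM. Interferon response genes had a median of 0.09, with 35 of 59 higher. The priming list had a median of -0.34 against -0.20 to 0.26 in random lists, with 13 of 22 lower, and the erythroid list 0.53 against -0.40 to 0.49 (camera adjusted p = 0.463 and 0.687).

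In edgeR 0 of 12132 genes passed for Nfat5 loss (smallest adjusted p = 1), and 338 had an unadjusted p under 0.05 where chance gives 607. DESeq2 called 166 genes, limma-voom 0, and limma-voom with genotype as a random block 5. None of 17 lists passed in camera, where the lowest adjusted p was 0.289, that of the osmotic stress list, and edgeR called 0 genes adjusted over the list alone. Median, mean and test differed in sign for 1 list, mast cell and basophil genes (-0.08, 0.42 and up). HSC and MPP libraries of a genotype may come from the same mice, which the labels do not say. P-values for genotype would be too small if such libraries were positively correlated. The correlation estimated by limma was -0.302, but with 4 genotypes and both factors varying between them it cannot rule out a positive one. A negative value makes errors for genotype smaller. With it, genes at an unadjusted p under 0.05 in limma-voom rose from 570 to 1187.

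Ifnar1 loss was examined by setting the libraries labelled IFNAR and DKO against those labelled WT and N5, again by labels that Ifnar1 itself did not follow. Type I interferon response genes fell together in the libraries labelled Ifnar1-deficient, with 47 of 59 measured members lower and a median log2 difference of -0.69 (mean -1.40; camera adjusted p = 1.30e-11). The list median was -0.85 and -0.52 in the HSC pairs and -0.79 and -0.77 in the MPP pairs, and 24 members were lower in all 4 pairs against 1 higher in all 4. B cell markers lay the other way, with a median of 1.33 against -1.05 to 0.82 in random lists and 6 of 7 measured members higher (camera adjusted p = 0.277), as did neutrophil markers, with 0.71 against -0.50 to 0.41. Pair medians were uneven, at 0 and 5.61 in HSC and 0.25 and 0.47 in MPP for B cell markers, and at 0.57 and -0.47 in HSC and 0.48 and 2.64 in MPP for neutrophil markers, where the pair of 2.64 set DKO against the low library labelled N5. Irf9, a transcription factor gene of the interferon response, had 43.1 ± 8.07 against 150 ± 63.9 CPM (mean ± SD, n = 4 libraries per side). Here too each side holds HSC and MPP libraries, and the SDs include the difference between cell types.

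Further members called adjusted over the list alone were lower in all 4 pairs as well. Ifi27 had 34.8 ± 13.2 against 151 ± 36.9 CPM, and the ubiquitin-like modifier gene Isg15 had 0 against 4.27 ± 1.74 CPM, at least 55.6-fold lower. Ly6a, which encodes the LSK sorting marker Sca-1, had 89.3 ± 46.2 against 194 ± 92.0 CPM, and Lgals3bp had 326 ± 117 against 459 ± 149 CPM. Not passing on that scale, the antiviral gene Oas2 had 0.276 ± 0.552 against 25.4 ± 6.09 CPM, and Ifit3 1.28 ± 2.56 against 12.3 ± 3.70 CPM. Ifi209 lay the other way at 28.1 ± 27.7 against 2.33 ± 4.67 CPM. Of the 5 genes of smallest p, none of which passed over all genes, Ifi27 had a log2 fold change of -2.17 (SE 0.33), and 3 lay outside the interferon list. Those 3 were Ssbp2 at 124 ± 6.54 against 264 ± 43.6 CPM, Nhsl2 at 0.00528 ± 0.0106 against 25.7 ± 3.85 CPM, and Csad, an enzyme gene of taurine synthesis, at 37.3 ± 24.0 against 103 ± 44.99 CPM. All 5 were lower in 4 of 4 pairs.

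Other groups did not pass for Ifnar1 loss. Antigen presentation genes had a median of -0.20 against -0.13 to 0.09 in random lists, lower in 3 of 4 pairs (adjusted p = 0.480 by camera). Among them H2-Q7 had 584 ± 197 against 866 ± 349 CPM and H2-T22 140 ± 88.4 against 245 ± 93.8 CPM. The class II transactivator gene Ciita lay the other way at 43.7 ± 29.3 against 8.29 ± 5.43 CPM. Neutrophil genes had a median of 0.71 (adjusted p = 0.140 by camera), with the collagenase gene Mmp8 at 9.24 ± 5.80 against 0.0496 ± 0.0993 CPM. Megakaryocyte genes had 11 of 11 members lower in the fit, with a median of -0.32 against -0.60 to 0.47 in random lists (adjusted p = 0.277 by camera). Of these members, 0 were lower in all 4 pairs. The p53 targets had a median of -0.51 against -0.46 to 0.38 in random lists, lower in 4 of 4 pairs (adjusted p = 0.445 by camera). The nucleolar gene Nop2 had 213 ± 32.7 against 115 ± 40.0 CPM, higher in 4 of 4 pairs, and the NF-kB inhibitor gene Tnfaip3 3.34 ± 6.67 against 48.4 ± 32.5 CPM.

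Camera called 1 of 17 lists for Ifnar1 loss, the interferon list, and kept it with an estimated correlation (adjusted p = 0.0143 with an estimated correlation). Random lists matched on expression gave medians from -0.16 to 0.13. In edgeR 0 of 12132 genes passed over all genes (smallest adjusted p = 0.992), 398 had an unadjusted p under 0.05 where chance gives 607, and 6 interferon genes passed adjusted over the list alone. DESeq2 called 233 genes, limma-voom 1, limma-voom with genotype as a random block 17, and bias-adjusted edgeR 1. Median, mean and test did not share a sign for 7 lists, none past the test, among them priming genes (-0.16, 0.22 and up) and NF-kB inflammation (0.11, -0.57 and down). The possible sharing of mice between HSC and MPP libraries applies to these p-values too.

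**Figure D3:**
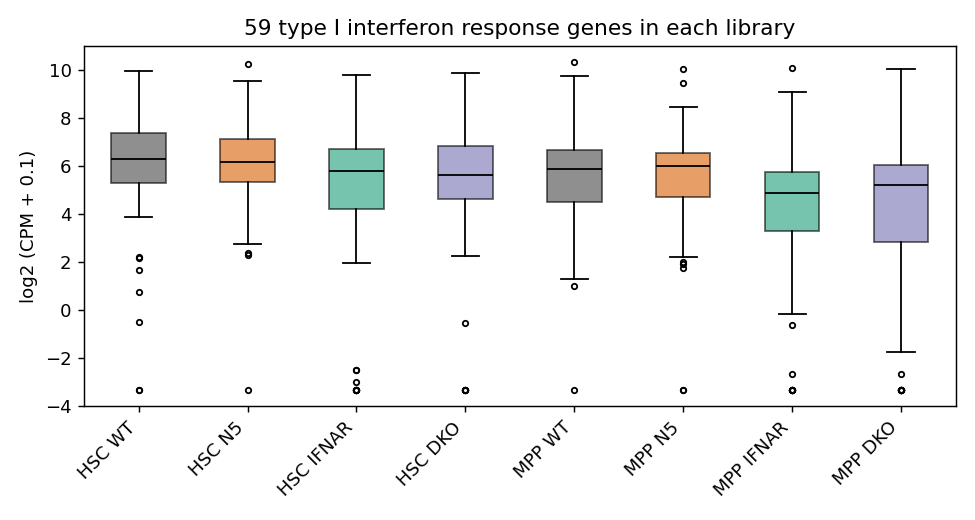
Log2 CPM (with 0.1 added) of 59 type I interferon response genes in each library, as boxes with the median and quartiles, whiskers to the last value within 1.5 interquartile ranges, and points beyond. Within each cell type the medians of the libraries labelled IFNAR and DKO lie below those labelled WT and N5 while the boxes overlap, and the list median for Ifnar1 loss was -0.69.

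The Nfat5 by Ifnar1 interaction asked whether the effect of Nfat5 loss differed with and without the receptor. No gene or list passed, and the genes of smallest p are given as levels in the libraries labelled WT, N5, IFNAR and DKO. Capn5, a calpain protease gene, had 146, 60.2, 46.0 and 155 CPM in HSC and 154, 71.6, 49.2 and 156 CPM in MPP. Axl, a receptor tyrosine kinase gene, had 62.3, 49.7, 45.5 and 0 CPM in HSC and 33.3, 24.6, 28.0 and 0 CPM in MPP. Vdr, the vitamin D receptor gene, had 16.9, 21.4, 0 and 109 CPM in HSC and 19.5, 6.25, 0 and 40.2 CPM in MPP. Bcas3 had 225, 48.0, 19.5 and 70.7 CPM in HSC and 90.5, 21, 11.6 and 40.1 CPM in MPP, and Tesk2 had 19.4, 0.03, 0.13 and 16.2 CPM in HSC and 26.8, 0.04, 0.08 and 20.3 CPM in MPP. In edgeR 0 genes passed (smallest adjusted p = 1), 404 had an unadjusted p under 0.05, DESeq2 called 393 and limma-voom 0. The lowest adjusted p of a list in camera was 0.270, and 0 members passed adjusted over the list alone. Median, mean and test did not share a sign for 5 lists.

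The remaining interactions asked whether either loss acted differently in HSC and MPP. For Nfat5, neutrophil genes differed between the cell types by camera at its preset correlation, with 11 of 11 measured members positive and a median difference of effects of 2.18 (HSC minus MPP). Camera gave adjusted p = 0.0271, and the call was lost otherwise (adjusted p = 0.847 with an estimated correlation). In MPP, libraries labelled N5 against WT, the granule gene Ltf had 19.0 against 217 CPM, Ngp 25.6 against 127 CPM and S100a8 36.7 against 103 CPM. In HSC these were 108 against 248, 138 against 106 and 157 against 80.8 CPM. In MPP labelled DKO against IFNAR, where Nfat5 loss was also compared, Ltf had 114 against 141 CPM, Ngp 172 against 62.0 CPM and S100a8 165 against 148 CPM. Of genes with smallest p, Tgm2, a transglutaminase gene, had 839, 922, 540 and 834 CPM in HSC labelled WT, N5, IFNAR and DKO, and 23.1, 0, 15.4 and 0 CPM in MPP. Irf8, a monocyte and dendritic cell regulator gene, had 0.03, 13.3, 0 and 15.7 CPM in HSC and 86.9, 143, 166 and 67.9 CPM in MPP. Ms4a3 had 2.43, 0, 5.08 and 0 CPM in HSC and 142, 69.8, 237 and 123 CPM in MPP. Cnn3 had 0, 14.1, 0 and 19.1 CPM in HSC and 92.3, 63.4, 63.2 and 45.1 CPM in MPP, and Epb41l3 had 73.4, 0, 23.4 and 0 CPM in HSC and 91.6, 63.3, 76.1 and 56.0 CPM in MPP. In edgeR 0 genes passed over all genes (smallest adjusted p = 0.133, for Tgm2), 536 had an unadjusted p under 0.05, DESeq2 called 585 and limma-voom 0. Adjusted over the list alone, edgeR called the priming genes Irf8 and Ms4a3 and the megakaryocyte gene Gata1. Median, mean and test did not share a sign for 6 lists.

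For Ifnar1, the genes of smallest p by cell type included Panx1, a membrane channel gene, with 57.6, 62.9, 0 and 0 CPM in HSC labelled WT, N5, IFNAR and DKO, and 75.9, 74.9, 71.4 and 69.1 CPM in MPP. Jchain, the joining chain gene of secreted antibodies, had 63.1, 13.3, 0 and 0 CPM in HSC and 185, 71.5, 311 and 178 CPM in MPP. Il18rap, an interleukin 18 receptor gene, had 18.5, 28.2, 0 and 0 CPM in HSC and 71.6, 98.3, 62.3 and 71.7 CPM in MPP. Wrnip1 had 0, 0, 95.5 and 50.8 CPM in HSC and 56.6, 94.3, 11.3 and 8.30 CPM in MPP, and the helicase gene Blm had 0.03, 0, 37.2 and 14.1 CPM in HSC and 89.6, 33.8, 108 and 21.6 CPM in MPP. In edgeR 0 genes passed over all genes (smallest adjusted p = 0.451), 585 had an unadjusted p under 0.05, DESeq2 called 607 and limma-voom 0. No list passed in camera (lowest adjusted p = 0.0717). Adjusted over the list alone, edgeR called the interferon genes Ifi44 and Oas3, the mast cell gene Cpa3, and Gata2 in both lists that hold it. Median, mean and test did not share a sign for 4 lists.

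Single libraries were then set side by side, with no test and no replicate check, to ask how libraries of different labels differed within a cell type. The genes named were picked for going the same way in HSC and MPP. Differences of 2-fold or more were common, at 39.2% of genes with at least 10 CPM in HSC and 25.7% in MPP for N5 against WT. For DKO against IFNAR the shares were 39.2% and 31.4%. Between the libraries labelled N5 and WT, Acad11, a fatty acid oxidation gene, had 92.1 against 0.06 CPM in HSC and 41.7 against 0 CPM in MPP, at least 420-fold higher in MPP. Zfp438 had 44.6 against 0 CPM in HSC and 22.5 against 0 CPM in MPP, at least 513-fold and 226-fold higher. Such bounds cover counting error only. Values at the floor in HSC were far more frequent than counting gives, at 7.95% among genes of 10 to 50 CPM. Tctn3, a gene of the primary cilium, had 47.03 against 0 and 17.7 against 0 CPM, at least 541-fold and 179-fold higher. Herc2 had 52.0 against 0 CPM in HSC and 54.6 against 0.13 CPM in MPP, and Ccdc186 25.02 against 0 and 35.8 against 0 CPM. The genes higher under N5 were not particular to it, since each also had counts in HSC labelled IFNAR, with Nfat5 intact by label. There Acad11 had 123 CPM in HSC and 24.2 CPM in MPP, Zfp438 27.0 and 28.45 CPM, and Tctn3 36.15 and 0 CPM. Srd5a1, a steroid reductase gene, lay the other way at 0 against 44.9 CPM in HSC and 0 against 28.4 CPM in MPP, at least 458-fold and 269-fold lower. Zswim3 had 0 against 22.95 and 0 against 46.1 CPM, Far2 0 against 19.1 and 0.07 against 42.4 CPM, Hspbap1 0 against 23.7 and 0 against 12.1 CPM, and Zfp677 0 against 23.1 and 0 against 11.02 CPM. Under DKO, also Nfat5-deficient by label, HSC and MPP had 17.6 and 0 CPM for Srd5a1, and 52.7 and 12.5 CPM for Zswim3. Far2 had 1.69 and 0.03 CPM there, Hspbap1 12.3 and 0 CPM, and Zfp677 0 and 9.03 CPM. Osmotic stress genes had medians of -1.35 in HSC (9 of 10 lower) and -0.77 in MPP (7 of 10 lower), both below the central 95% of random lists. Between IFNAR and WT they had medians of -0.63 and -0.33 (7 of 10 lower in each cell type), inside that range. Further lists outside it between N5 and WT were antigen presentation in HSC (0.27 against -0.29 to 0.23), and proliferation (-0.33 against -0.19 to 0.16) and neutrophil genes (-2.17 against -0.63 to 0.60) in MPP.

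Between the libraries labelled DKO and IFNAR, Vdr had 109 against 0 CPM in HSC and 40.2 against 0 CPM in MPP, at least 1420-fold and 486-fold higher. The Toll-like receptor adaptor gene Ticam1 had 34.2 against 0 and 35.1 against 0 CPM, at least 446-fold and 425-fold higher. Rtl6 had 54.7 against 0 and 62.4 against 0 CPM, Reep6 33.9 against 0 and 29.8 against 0 CPM, and Aasdh 22.8 against 0 and 40.7 against 0 CPM. Each of the genes higher under DKO here also had counts under WT in both cell types, among them Vdr (16.9 and 19.5 CPM). Axl had 0 against 45.5 CPM in HSC and 0 against 28.0 CPM in MPP, at least 718-fold and 329-fold lower. Caprin2 had 0 against 117 and 0 against 13.3 CPM, Zfp52 0 against 52.5 and 0 against 32.9 CPM, Zfp583 0 against 25.1 and 0 against 49.2 CPM, and Tubd1 0 against 47.7 and 0 against 24.2 CPM. These zeros were not particular to DKO in HSC. There Caprin2 and Zfp52 also had 0 CPM under WT and N5, and Zfp583 and Tubd1 had 0 CPM under N5. Axl had 62.3 and 49.7 CPM in HSC under WT and N5. In MPP each of the genes lower under DKO had counts under WT and N5. Osmotic stress genes had medians of 0.03 in HSC (5 of 10 higher) and -0.23 in MPP (6 of 10 lower) between these labels, both inside the central 95% of random lists (-0.86 to 1.02 and -0.71 to 0.80). Lists outside it were priming in HSC (-0.41 against -0.39 to 0.47) and NF-kB inflammation in MPP (0.70 against -0.57 to 0.65). Antigen presentation in HSC (-0.04), and proliferation (-0.12) and neutrophil genes (0.15) in MPP, lay inside it. Genes at 2-fold or more in both cell types went the same way in HSC and MPP in 49.5% of cases for N5 against WT (544 of 1100, 95% interval 46.5 to 52.5) and in 667 of 1334 for IFNAR against WT (95% interval 47.3% to 52.7%). The share was 48.6% for DKO against WT (638 of 1312), 48.8% for DKO against N5 (588 of 1204) and 52.2% for DKO against IFNAR (676 of 1296). These shares lie near the even split that unrelated directions would give. The intervals treat genes as independent, although genes of the same libraries are not, and they do not measure spread between libraries. Across genes, log2 ratios in HSC and MPP had r = 0.0135 for N5 against WT and 0.0334 for DKO against IFNAR. The genes named above were picked for going the same way, so that agreement shows no effect of a label.

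**Figure D4:**
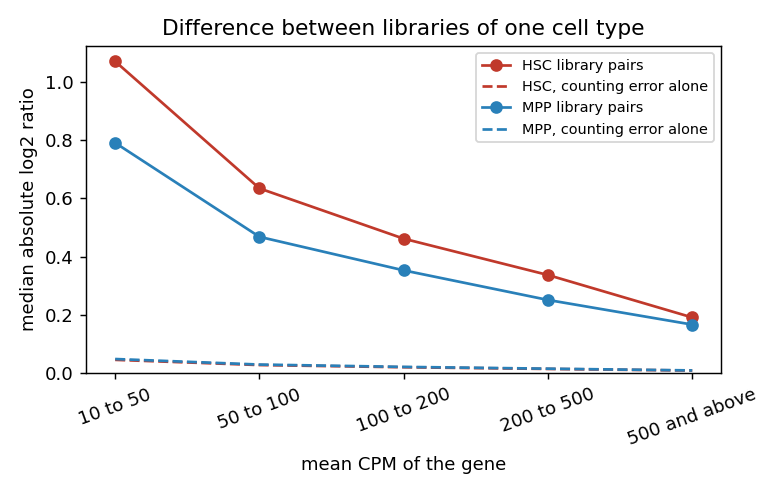
Median absolute log2 ratio between libraries of a cell type (solid lines) by mean CPM of the gene over all 8 libraries, with the ratio expected from counting error alone (dashed lines). At 10 to 50 CPM the ratio was 1.07 in HSC and 0.79 in MPP, against 0.04 and 0.05 from counting.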

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

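The tests in this part were chosen after the result was seen, except that over abundant interferon members and that with libraries thinned to equal depth, which were set down beforehand.

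Neutrophil markers were picked out because the Nfat5 effect on them differed between HSC and MPP in the interaction test (camera adjusted p = 0.0271 at the preset correlation; adjusted p = 0.847 with an estimated correlation). As large a result came from 7 of 22 distinct splits of the libraries, so chance cannot be excluded (-log10 p of 2.80 against 7.496 in the highest other split). In the MPP library labelled N5, 11 of 11 measured markers were lower than in the one labelled WT, among them Ltf (19.0 against 217 CPM), Ngp (25.6 against 127 CPM) and Camp (12.3 against 44.8 CPM), all made by neutrophils and their late precursors.

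Thinning all libraries to the smallest total left the median at -1.88 but decides nothing, since the totals of both libraries were close already (28871700 counts under N5 and 30648600 under WT). Neutrophil RNA carried past the LSK gate, which would remove mature neutrophils, would lower all markers by similar ratios, and 11 of 11 were lower. It may explain the markers and cannot be told apart there, since the ratios were uneven (log2 -3.51 to -1.01 among abundant members). Of the 12 listed genes, 11 passed the expression filter over all 8 libraries, which does not show that these progenitors made them. In the MPP library labelled N5, Cd177 and Mmp8 had 0 CPM. Genes of immature granulocyte precursors (Mpo, Elane, Prtn3, Ctsg and Ms4a3) had a median of -0.90, but they were picked after their values were seen and so decide nothing, and the whole priming list lay inside random lists (-0.16 against -0.33 to 0.29). Fewer granulocyte-primed cells in that pool remains an untested hypothesis resting on 1 library. Between cell types the neutrophil markers did not follow priming. In HSC versus MPP they had a median of 0.14 (7 of 11 higher, 4 lower). The priming list, which holds those precursor genes, had -5.85 (22 of 22 lower). Marker medians by pair were -0.26, 2.43, -0.67 and -0.52, against -5.32 to -3.71 for priming. The values argue against granulocyte-primed cells as the main source of the markers, without showing another source. The MPP library labelled DKO goes against a common effect of the Nfat5 label. There 8 of 11 markers were higher than under WT (median 0.59) and 7 of 11 higher than under IFNAR (median 0.15).

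The interferon list was lower in the libraries labelled Ifnar1-deficient more strongly than in any other split (1 of 29 distinct splits as large, -log10 p of 12.1 against 5.14 in the highest other split), so chance can be excluded at 0.05 for this list only if libraries of a genotype vary independently, since no more than 3 splits keep genotypes whole, too few for such a share. Loss of low-count transcripts is argued against, because 34 members with a mean of at least 50 CPM had a median of -0.53, below that of random lists (-0.17 to 0.12). Exchanged Ifnar1 labels cannot be told apart from correct ones, since a lower list mean in all 4 libraries labelled deficient than in both others of their cell type restates the pattern. In 4 of 4 disjoint pairs the list median lay below that of random lists, consistent with absent type I interferon receptor signalling, a hypothesis read from the same data. Ifnar1 counts do not settle it, because they did not follow the labels and the deleted exons are not given in the sources used here.

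Well-expressed genes were often at the count floor in single libraries, with 7.95% of HSC values at 3 or fewer counts among 4541 genes with a mean of 10 to 50 CPM in HSC, and 2.61% among 4364 such genes in MPP. Depth is argued against, since counting error at these totals gives 1.33e-129%. Few starting RNA molecules per library is consistent with the fall of the squared coefficient of variation with the mean, at a log-log slope of -0.886 in HSC and -0.851 in MPP. Bursts of transcription in a small number of sorted cells were not separated from lost molecules here, and no biological explanation was tested. Genes such as Zfp438, Vdr and Axl, at 0 in some libraries and well expressed in others, belong to the expression range where such values occurred. Among genes with a mean of 50 to 100 CPM the share fell to 0.367% in HSC and 0.0671% in MPP. Acad11 belonged to that higher range in HSC.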

How the results depend on the processing

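The tests with bias-adjusted edgeR, with genes of at least 50 CPM and with limma-trend were chosen only after the result was seen. No result reversed, and Dntt and Cd34 kept direction and call in all settings that used every library. For HSC versus MPP, edgeR gave 2 genes, and the count was 23 with 10 CPM in 4 libraries, 1880 with DESeq2, 156 with limma-voom, 207 without the genotype block, 32 with Ifnar1 and Nfat5 terms, 107 bias-adjusted, 105 at 50 CPM and 102 with limma-trend. Leaving out a library gave 0 to 0, with Dntt and Cd34 lost in all 8 fits, each with 1 residual degree of freedom fewer, while their log2 folds stayed between -15.17 and -16.92 and between -2.52 and -2.66. Its 8 lists became 5 with an estimated correlation. With fry there were 8, with oxidative phosphorylation in and antigen presentation out. DESeq2 called 166 genes for Nfat5 loss, 233 for Ifnar1 loss, 393 for Nfat5 by Ifnar1, 585 for Nfat5 by cell type and 607 for Ifnar1 by cell type, where edgeR called 0. Its simulated calls were 60.6% to 80.9% false. With genotype as a random block (consensus correlation -0.302), limma-voom called 5 genes for Nfat5 loss (Slamf8, Ppip5k1 and Ston2 up, Mlf1 and Hif3a down) and 17 for Ifnar1 loss. A negative correlation makes errors for genotype smaller. Genes at an unadjusted p under 0.05 rose from 570 to 1187 for Nfat5 loss and from 602 to 1249 for Ifnar1 loss. Counts of HSC and MPP summed per genotype gave 0 genes for both in edgeR. For Ifnar1 loss limma-voom alone called 1 gene (Mpo, up) and bias-adjusted edgeR 1 (Rtp4, down). At 50 CPM, Nfat5 by cell type gave 1 gene (Tgm2) and Ifnar1 by cell type 3 (Jchain, Panx1 and Igha). These genes were named after their values were seen.

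For Ifnar1 loss, leaving out a library gave 1 to 2 lists (2 without HSC N5, HSC IFNAR or MPP WT). For Nfat5 by Ifnar1 it gave 0 to 1 (1 without HSC N5 or MPP DKO), and for Ifnar1 by cell type 0 to 1 (1 without HSC WT or MPP WT). Nfat5 by cell type had 0 lists with an estimated correlation, 0 with fry, and 0 to 1 on leaving out a library. Its neutrophil list had adjusted p = 0.847 with an estimated correlation, 0.589 with fry, and 4.31e-06 to 0.761 on leaving out a library, lost without HSC N5 (0.507), HSC IFNAR (0.4998), MPP WT (0.395) or MPP N5 (0.761). The antigen presentation list in HSC versus MPP had adjusted p = 0.0822 with fry. The share of genes going the same way for DKO against WT was 43.4% at 50 CPM, against 48.6%. Of the named-gene values in settings with every library, 227 kept direction and side of the threshold and 56 newly passed it. The cause was not tested for any of these differences except where fewer libraries or genes entered. Depth limits little here, since genes of 10 CPM had at least 289 counts.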

Other observations

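In this part, all tests except those on genes at the floor in 4 libraries and on chromosomal neighbours were chosen after the result was seen, and the genes named were chosen after their values were seen.

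Genes at 3 or fewer counts in every library of a cell type and at 10 CPM or more in every library of the other followed the sort closely. There were 25, of which 10 were at 10 CPM or more in HSC and 15 in MPP. Those of HSC included Cavin2, the cilium genes Evc and Evc2, the guanylate-binding protein genes Gbp4 and Gbp8, and the tight junction gene Ocln. Those of MPP included Dntt, Ccr2, F13a1, the interleukin 10 receptor gene Il10ra, Siglecf and Pdgfrb. No more than 2 such genes arose in any other of the 35 splits (1 as large, the real one), so chance can be excluded for the cell types if the libraries vary independently. By the Nfat5 label there was 1 such gene, Hif3a, an oxygen-response factor gene with 15.8, 0, 41.4 and 0 CPM in the HSC libraries labelled WT, N5, IFNAR and DKO and 15.5, 0, 12.5 and 0 CPM in MPP. By the Ifnar1 label there was 1 as well, Nhsl2, already described. For each label 20 of 35 splits gave as many, so chance cannot be excluded. The highest other split had 25, that of the cell types, and it points to that structure of the samples.

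In the MPP libraries, the granulocyte genes Mpo, Elane and Ctsg were higher under the label IFNAR (8757, 1397 and 1082 CPM) than under WT (6182, 782 and 627 CPM), and lower under N5 (3743, 418 and 319 CPM). Under DKO they lay above WT (8026, 1144 and 879.8 CPM), as did Prtn3 (504 against 444 CPM), while Ms4a3 lay below (123 against 142 CPM). In HSC, Mpo and Elane had 0 CPM under DKO against 147 and 37.3 CPM under WT. These are values of single libraries.

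Splits that give the same fit once the other terms are in the model were counted once. For HSC versus MPP this left 20 distinct splits, too few for a share under 0.05. The 2 genes called were matched by 1 of them (the real one; highest other 0) and the 8 lists by 2 (highest other 9, in a split that keeps 3 of the 4 HSC libraries together and so holds much of the difference between cell types). The 0 genes called by edgeR for Nfat5 loss and for Ifnar1 loss were matched in 29 of 29 splits (highest other 0), and the 0 genes of each of the 3 interactions in 22 of 22 (highest other 0), so these splits decide nothing, because every split matches a count of 0. The counts at an unadjusted p under 0.05 and by other tools stand beside each comparison. For the single list called in Ifnar1 loss, 16 of 29 splits called as many (highest other 2), and for the single list of the Nfat5 by cell type interaction 7 of 22 did (highest other 1), so chance cannot be excluded for either number of lists.

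A stretch of donor chromosome carried along with a targeted allele could shift genes near it. The 50 tested genes on either side, as far as the order was known (12112 of 12132 genes matched), had a median absolute t of 0.869 near Ifnar1 (86 genes, random lists 0.593 to 0.982) and of 0.832 near Nfat5 (100 genes, random lists 0.600 to 0.961). Both lie inside the range of random lists, which had been set down as the result against such a stretch. That bound was wrong, because a median over 86 to 100 neighbours leaves a shorter stretch open, so a short one cannot be told apart from none.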
